A study of Danio rerio with 12 samples.

How the data were processed

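RNA selected for polyadenylation was measured in 12 libraries of zebrafish larvae at 3 days post-fertilization. There were 4 libraries each of wild type (WT), yap mutant and yap taz mutant, and groups were taken from the sample titles. Per the submitters' processing notes RNA was extracted with Trizol and RNeasy columns, sequenced on an Illumina HiSeq and processed with STAR 2.3.0e and HTSeq 0.6.0. Genome build, annotation release and strand setting are not given in the sources used here.

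The deposited table holds raw counts per Ensembl gene, whole numbers with no normalization, for 25473 gene identifiers, of which 1049 were 0 in every library. Symbols were taken from the supplied list of names, which gives 22531 of the identifiers a symbol, and 3402 identifiers share a symbol with another. That list often gives a family or human-style symbol without the zebrafish paralogue letter, so a symbol such as SLC2A1 does not say which paralogue is meant and the identifier does.

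Genes were kept with filterByExpr (minimum count 10, minimum total 15, by group), which left 19493. Libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with 1 coefficient per genotype was fitted to all 12 libraries with edgeR 4.0.16 under R 4.3.3, without a block. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. Fold changes are log2 of the first group over the second, given ± SE from the model. Levels are counts scaled by library size and TMM factor to the usual common total (CPM), given ± SD over 4 libraries, and log2 CPM used a prior count of 2. Total counts were 7028251 to 8657381 per library, so that 3 counts, the most that a count of 0 allows, amount to 0.347 to 0.427 CPM. Such floors cover counting error only, and p-values measure only the spread between these libraries.

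The 41 gene lists, of pathways and of cell types of the larva, the alternatives and the rule for named genes were written before the data were examined. Of their 1303 symbols 1235 matched the table, by symbol, by current symbol or by family symbol without the paralogue letter, and 30 of the 1292 genes matched are in more than 1 list. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with p adjusted over the 41 lists of a comparison. Beside it were run camera with an estimated correlation and fry. By fry, 15, 27 and 7 lists moved on balance one way at an adjusted p under 0.05 in the yap mutant against WT, the yap taz mutant against WT and the yap taz mutant against the yap mutant, and 36, 40 and 35 held changes in either direction. Neither fry test compares a list with other genes.

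Named genes were YAP1 and WWTR1, and, among called genes with a mean log2 CPM of at least 1 and groups that did not overlap, the 8 largest and 8 smallest fold changes against WT (6 and 6 between the mutants). Also named were up to 4 called members of called lists by smallest p, up to 2 of other lists, and up to 4 members of the YAP/TAZ target, glucose transporter, glycolysis, purine and pyrimidine lists whether called or not. Names of clones or loci were left out. A prefix of clones counted as such only before digits, and FAM and LOC wherever they opened a name. The text gives values for part of these genes, and some are not reported here, part of which were left out of the test for libraries that stand apart.

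The titles number the libraries 1 to 4 in each genotype without saying whether the numbers pair them. This was checked by correlating each library's deviations from its group mean across genes. WT and yap mutant libraries with the same number correlated at 0.18, 0.306, 0.282 and 0.388, all above the 0.1 set for pairing. Values there still lack a block. Gene counts and the lost list call with it are given, not member counts. For WT with the yap taz mutant the values were 0.166, 0.103, 0.0717 and -0.00482, and between the mutants all 4 were below 0.1, so these comparisons were not treated as paired.

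The alternatives were size factors of DESeq2 (RLE) or upper-quartile scaling in place of TMM, no filter, a filter of 1 CPM in at least 4 libraries, the 8 libraries of each pair of groups alone, the replicate number as a block, each library left out in turn, limma-voom, DESeq2 1.42.0 with its own test, a test against a minimum fold of 1.5 (glmTreat), and the estimated correlation. The block with 8 libraries alone was chosen after seeing the data. Every other split of the 8 libraries of a comparison into 4 and 4 was fitted too, 35 with the real one.

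The procedure was tested on known changes simulated at these libraries' depth and spread. At true folds of 1.5, 2 and 3 it recovered 43.3%, 83.6% and 93.9% of changed genes for the yap mutant against WT, 61.2%, 76.1% and 95.5% for the yap taz mutant against WT, and 46.3%, 74.6% and 84.8% between the mutants. It made 5, 22 and 13 false calls, gave 0 wrong signs and called the moved list but not the still one. With uncorrelated genes it does not test correlated lists. Plots used matplotlib 3.10.9 and Python 3.11.15.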

Results

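Polyadenylated RNA of whole zebrafish larvae was sequenced at 3 days post-fertilization. The 12 libraries came from wild-type (WT) larvae, larvae homozygous for a yap mutation, and larvae homozygous for mutations in both yap and taz, with 4 libraries per genotype. Yap and Taz are the transcriptional co-activators restrained by the Hippo kinase pathway. A whole-larva library mixes the RNA of every organ, so each value is an average over tissues. Total counts ranged from 7028251 to 8657381 per library, with 8261698 ± 387091 (SD, n = 4) in WT, 7934988 ± 88138 in the yap mutant and 7598050 ± 440680 in the yap taz mutant. The 10 most abundant genes held 8.09 ± 0.275% of the counts in WT, 8.99 ± 0.314% in the yap mutant and 9.85 ± 0.726% in the yap taz mutant. Genes of the mitochondrial genome held 3.56 ± 0.367%, 3.14 ± 0.237% and 2.59 ± 0.0689% in the same order. The first principal component of log2 counts scaled by library size to the usual common total (CPM) held 44.7% of the variance. On it the 4 WT libraries scored -48.6 to -27.4, the 4 yap mutant libraries -16.1 to 21.3, and the 4 yap taz mutant libraries 31.2 to 39.6.

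Transcripts of the targeted genes were still present in the mutants. YAP1 (ENSDARG00000068401) fell in the yap mutant, from 88.4 ± 7.99 CPM (SD, n = 4) to 59.9 ± 7.62 CPM, and stood at 69.9 ± 3.91 CPM in the yap taz mutant. The log2 fold changes against WT were -0.56 ± 0.0943 (SE, adjusted p = 0.00149, edgeR quasi-likelihood test) and -0.34 ± 0.0939 (adjusted p = 0.0126), and every library of both mutants lay below every WT library. WWTR1 (ENSDARG00000067719), the gene that encodes Taz, was measured at 7.03 ± 1.33 CPM in WT, 10.4 ± 1.17 CPM in the yap mutant and 5.56 ± 0.886 CPM in the yap taz mutant. It fell in the yap taz mutant against the yap mutant (-0.90 ± 0.17, adjusted p = 0.00673), while its difference from WT did not pass the test (-0.35 ± 0.175, adjusted p = 0.156). Its rise in the yap mutant against WT (0.56 ± 0.162, adjusted p = 0.0425) did not pass the test without WT 2, WT 3, WT 4, yap mutant 1, yap mutant 2, yap mutant 4, yap taz mutant 2 or yap taz mutant 3 (adjusted p = 0.053 to 0.122), nor without a filter on low counts (adjusted p = 0.0594) or with the 8 libraries of WT and yap mutant alone (adjusted p = 0.0685). The kind of mutation is not given in the sources used here, so a lower RNA level is neither required nor excluded by the labels. No library of one genotype carried the YAP1 and WWTR1 values of another: in the yap mutant all 4 libraries had YAP1 below the WT range and WWTR1 above the ranges of both other groups.

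**Figure D1:**
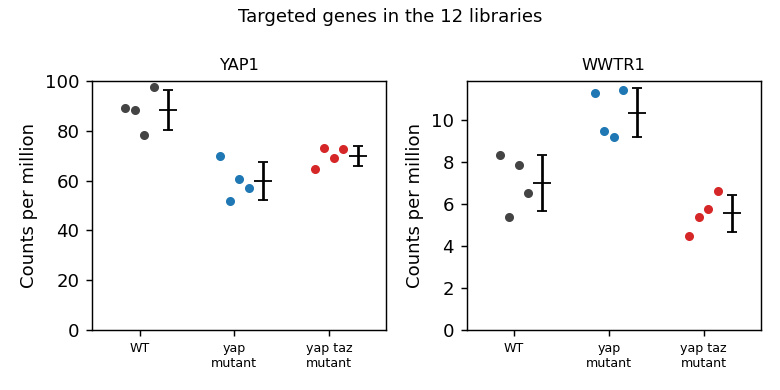
CPM of YAP1 (left) and WWTR1 (right) on linear axes from 0, with 1 point per library and the mean ± SD of the 4 libraries beside the points of each genotype. YAP1 ranged from 78.3 to 97.8 CPM in WT, 51.7 to 69.8 in the yap mutant and 64.6 to 73.1 in the yap taz mutant, and WWTR1 from 5.40 to 8.34, 9.22 to 11.4 and 4.48 to 6.61.

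In the yap mutant 21 of 37 mitosis and 24 of 48 photoreceptor genes were lower, while 14 of 32 heat shock and immediate-early and 14 of 32 myeloid genes were higher. The comparison of the yap mutant with WT asks what differs in larvae homozygous for the yap mutation alone. cbx7a (ENSDARG00000038025), a Polycomb-group gene, rose from 6.96 ± 2.12 CPM to 78.7 ± 26.5 CPM (3.51 ± 0.25, adjusted p = 7.08e-07), and FOSL1 (ENSDARG00000015355), an AP-1 transcription factor gene, from 1.46 ± 0.742 CPM to 12.4 ± 6.11 CPM (3.09 ± 0.397, adjusted p = 0.000155). In WT, where 3 counts amount to 0.347 to 0.386 CPM, 3 genes of secreted signals lay at or near that floor. The yap mutant had lepb (ENSDARG00000045548), a leptin, at 5.12 ± 3.71 CPM against 0.12 ± 0.00988 CPM, il11a (ENSDARG00000037859), an interleukin, at 5.66 ± 2.52 CPM against 0.146 ± 0.114 CPM, and il1b (ENSDARG00000098700), an inflammatory cytokine, at 3.85 ± 2.87 CPM against 0.409 ± 0.273 CPM. The largest falls among the genes named by rule were tgm1l3 (ENSDARG00000005913), a transglutaminase gene (-1.96 ± 0.412, adjusted p = 0.00782), and fabp10a (ENSDARG00000038439), the liver fatty-acid-binding protein gene, from 140 ± 39.2 CPM to 48.4 ± 19.5 CPM (-1.53 ± 0.246, adjusted p = 0.00107).

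In all, 1780 of 19493 genes tested differed between the yap mutant and WT at an adjusted p under 0.05, with 1115 higher and 665 lower, of which 293 and 52 changed at least 2-fold (edgeR quasi-likelihood test, 4 against 4 libraries). In 13.3% of genes the 4 libraries of one group all lay above the 4 of the other, where chance gives 2.86%. The count was 2758 with the replicate number as a block (1561 higher, 1197 lower), 1163 from the 8 libraries of the 2 groups alone (765 and 398) and 142 against a minimum fold of 1.5 (138 and 4). Without single libraries it was 942 (without yap mutant 1), 954 (yap mutant 4), 1059 (WT 3), 1076 (WT 2) or 3041 (yap mutant 3). Of the 41 gene lists, camera with a preset correlation called 21 and with an estimated correlation 0 (6 at an unadjusted p under 0.05). Other splits of these 8 libraries called 5 to 22 lists. This limits list calls, and counts of correlated members were not so tested.

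The cell division genes called in the yap mutant were all lower. Of 37 mitosis genes 0 rose and 21 fell, or 0 and 34 with p adjusted over the list alone. The Mitosis list had a camera adjusted p = 4.2e-20, and adjusted p = 0.252 with an estimated correlation. Examples were hmgb2b (ENSDARG00000053990), a chromatin protein gene (-0.55 ± 0.104, adjusted p = 0.00372), ccnb3 (ENSDARG00000034855), a cyclin B gene (-0.65 ± 0.124, adjusted p = 0.00413), TPX2 (ENSDARG00000078654), a spindle assembly factor gene (-0.59 ± 0.114, adjusted p = 0.00441), and CDC20 (ENSDARG00000100741), an activator of the anaphase-promoting complex (-0.54 ± 0.105, adjusted p = 0.0049). Of 44 DNA replication genes 0 rose and 12 fell, or 0 and 26 with p adjusted over the list alone, among them MCM6 (ENSDARG00000057683) and MCM2 (ENSDARG00000102798) of the replicative helicase (-0.44 ± 0.0849, adjusted p = 0.00469, and -0.47 ± 0.108, adjusted p = 0.0129). The DNA replication list had a camera adjusted p = 2.51e-14, and adjusted p = 0.259 with an estimated correlation. The symbol MCM6 is shared by more than 1 gene of the table.

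Glucose and nucleotide genes, which the series title names, moved in both directions. Of 15 glucose transporter genes 3 rose and 1 fell, or 3 and 1 with p adjusted over the list alone (camera adjusted p = 0.287). The symbol SLC2A1 stands for 2 genes of the table: SLC2A1 (ENSDARG00000001437) fell from 8.46 ± 0.831 CPM to 4.27 ± 1.03 CPM (-0.99 ± 0.2, adjusted p = 0.00618), while SLC2A1 (ENSDARG00000007412) was higher (0.59 ± 0.171, adjusted p = 0.0415), a call lost without WT 2, WT 3, yap mutant 1, yap mutant 2, yap mutant 4, yap taz mutant 3 or yap taz mutant 4 (adjusted p = 0.053 to 0.147) and with upper-quartile scaling (adjusted p = 0.0512). The transporter gene slc2a3b (ENSDARG00000037861) rose (1.53 ± 0.323, adjusted p = 0.00783). Of 33 glycolysis genes 2 rose and 2 fell, or 2 and 2 with p adjusted over the list alone (camera adjusted p = 0.447), with the hexokinase gene HK2 (ENSDARG00000101482) higher (0.49 ± 0.114, adjusted p = 0.0135). In gluconeogenesis 2 rose and 1 fell of 13 (camera adjusted p = 0.357), and PCK1 (ENSDARG00000013522), its rate-controlling carboxykinase, rose from 135 ± 23.9 CPM to 335 ± 32.9 CPM (1.31 ± 0.122, adjusted p = 8.25e-06). In the pentose phosphate pathway 2 rose and 1 fell of 10 (camera adjusted p = 0.309), and the transketolase gene TKT (ENSDARG00000029689) fell (-0.52 ± 0.0934, adjusted p = 0.00268).

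Nucleotide synthesis genes moved in both directions. Of 19 genes of pyrimidine and deoxynucleotide synthesis 0 rose and 4 fell, or 0 and 4 with p adjusted over the list alone. The Pyrimidine and deoxynucleotide synthesis list had a camera adjusted p = 0.0124, and adjusted p = 0.259 with an estimated correlation. They included RRM1 (ENSDARG00000014017), the large subunit gene of ribonucleotide reductase (-0.61 ± 0.104, adjusted p = 0.0016), and TYMS (ENSDARG00000042894), the thymidylate synthase gene (-0.45 ± 0.115, adjusted p = 0.024), whose call was lost without WT 1, WT 3, yap mutant 2 or yap mutant 4 (adjusted p = 0.0607 to 0.0789). Of 17 purine synthesis genes 4 rose and 1 fell, or 4 and 1 with p adjusted over the list alone (camera adjusted p = 0.888). PPAT (ENSDARG00000004517), the first enzyme of the pathway (0.69 ± 0.156, adjusted p = 0.0125), and PAICS (ENSDARG00000033539), a later enzyme (0.81 ± 0.211, adjusted p = 0.026), were higher, the former not past the threshold without yap mutant 1 (adjusted p = 0.0501) and the latter not without WT 2, WT 3, yap mutant 1 or yap mutant 4 (adjusted p = 0.067 to 0.0884) nor with the 8 libraries alone (adjusted p = 0.0638). GLDC (ENSDARG00000035120) of the glycine cleavage system rose (1.45 ± 0.164, adjusted p = 5.42e-05), one of 20 serine and one-carbon genes of which 3 rose and 0 fell, or 6 and 2 with p adjusted over the list alone (camera adjusted p = 0.0734).

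Among genes of the eye more fell than rose. Of 48 photoreceptor genes 0 rose and 24 fell, or 0 and 26 with p adjusted over the list alone. The Photoreceptor list had a camera adjusted p = 2.54e-17, and adjusted p = 0.252 with an estimated correlation. The arrestin gene sagb (ENSDARG00000038378) fell from 74.8 ± 5.05 CPM to 43.1 ± 5.67 CPM (-0.79 ± 0.135, adjusted p = 0.00171), and the kinase gene grk1b (ENSDARG00000104685) from 61.5 ± 11.4 CPM to 33.8 ± 6.27 CPM (-0.86 ± 0.15, adjusted p = 0.00199). Of 34 lens genes 0 rose and 13 fell, or 0 and 15 with p adjusted over the list alone. The Lens list had a camera adjusted p = 4.81e-07, and adjusted p = 0.357 with an estimated correlation. Of 17 genes of the retinal pigment epithelium 1 rose and 5 fell, or 1 and 5 with p adjusted over the list alone, among them the retinoid isomerase gene RPE65 (ENSDARG00000007480) (-1.18 ± 0.172, adjusted p = 0.000488) and the retinaldehyde-binding protein gene rlbp1b (ENSDARG00000045808) (-1.21 ± 0.255, adjusted p = 0.00783). The Retinal pigment epithelium list had a camera adjusted p = 0.0029, and adjusted p = 0.252 with an estimated correlation. The symbol RPE65 is shared by more than 1 gene of the table. Of 65 neuronal genes 0 rose and 13 fell, or 1 and 16 with p adjusted over the list alone, with the beta-tubulin gene tubb5 (ENSDARG00000037997) (-0.75 ± 0.15, adjusted p = 0.00552) and the growth-cone gene gap43 (ENSDARG00000099744) (-0.42 ± 0.0942, adjusted p = 0.0112) lower. The Neuron list had a camera adjusted p = 0.000386, and adjusted p = 0.427 with an estimated correlation.

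Among immediate-early, stress and myeloid genes more rose than fell. Of 32 heat shock and immediate-early genes 14 rose and 0 fell, or 17 and 3 with p adjusted over the list alone. The Heat shock and immediate early genes list had a camera adjusted p = 1.31e-12, and adjusted p = 0.222 with an estimated correlation. The members named by rule were not chaperones: SOCS3 (ENSDARG00000026611), a cytokine signalling inhibitor gene (2.4 ± 0.134, adjusted p = 8.94e-08), and the AP-1 genes JUNB (ENSDARG00000074378) (2.2 ± 0.207, adjusted p = 9.35e-06), JUNB (ENSDARG00000104773) (1.63 ± 0.17, adjusted p = 2.41e-05) and FOSL2 (ENSDARG00000040623) (1.39 ± 0.149, adjusted p = 3.03e-05). Of 27 genes of the integrated stress response 8 rose and 0 fell, or 14 and 0 with p adjusted over the list alone, among them CEBPB (ENSDARG00000042725) (1.63 ± 0.199, adjusted p = 9.86e-05) and TRIB3 (ENSDARG00000016200) (0.71 ± 0.116, adjusted p = 0.00135). The Integrated stress response list had a camera adjusted p = 1.73e-05, and adjusted p = 0.252 with an estimated correlation. Of 28 p53-response genes 7 rose and 1 fell, or 12 and 2 with p adjusted over the list alone, led by the tumour necrosis factor receptor gene tnfrsf1a (ENSDARG00000018569) (1.18 ± 0.128, adjusted p = 3.46e-05). The p53 response list had a camera adjusted p = 0.00667, and adjusted p = 0.259 with an estimated correlation. Of 32 myeloid genes 14 rose and 0 fell, or 22 and 2 with p adjusted over the list alone, including the matrix protease genes MMP9 (ENSDARG00000042816) (3.16 ± 0.427, adjusted p = 0.000252) and mmp13a (ENSDARG00000012395) (2.85 ± 0.43, adjusted p = 0.000639) and the macrophage transcription factor gene IRF8 (ENSDARG00000056407) (1.33 ± 0.259, adjusted p = 0.00483). The Myeloid list had a camera adjusted p = 5.19e-11, and adjusted p = 0.252 with an estimated correlation.

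In the YAP/TAZ target signature more genes rose than fell. Of 30 such genes 8 rose and 1 fell (ANKRD1, narrowly), or 11 and 1 with p adjusted over the list alone. The YAP/TAZ target signature list had a camera adjusted p = 7.64e-06, and adjusted p = 0.252 with an estimated correlation. They included amotl2b (ENSDARG00000061948), an angiomotin-like scaffold gene, from 29.9 ± 2.87 CPM to 60 ± 13.7 CPM (1.01 ± 0.13, adjusted p = 0.000162), and CCN2 (ENSDARG00000042934), a matricellular protein gene, from 102 ± 5.79 CPM to 164 ± 26.8 CPM (0.69 ± 0.11, adjusted p = 0.00106). Of 29 Hippo pathway and TEAD genes 2 rose and 0 fell, or 2 and 0 with p adjusted over the list alone, a list call lost without yap mutant 1 (adjusted p = 0.0688). The Hippo pathway and TEAD list had a camera adjusted p = 0.0116, and adjusted p = 0.357 with an estimated correlation. Without single libraries mob1a (ENSDARG00000102320) lost its call in 3 fits (adjusted p = 0.0507 to 0.0563) and taok1b (ENSDARG00000098304) in 7 (0.0515 to 0.128), the latter also with the 8 libraries alone (adjusted p = 0.0778). Of 53 matrix genes 12 rose and 3 fell, or 15 and 3 with p adjusted over the list alone, with thrombospondin THBS1 (ENSDARG00000103775) (2.14 ± 0.223, adjusted p = 2.41e-05) and fibronectin FN1 (ENSDARG00000006526) (1.44 ± 0.208, adjusted p = 0.000431) higher, each symbol being shared by 2 genes. The Extracellular matrix list had a camera adjusted p = 0.0294, and adjusted p = 0.604 with an estimated correlation. That list call was lost without WT 1, WT 2, WT 3 or yap mutant 1 (adjusted p = 0.0605 to 0.145), with limma-voom (adjusted p = 0.053) and with the 8 libraries alone (adjusted p = 0.056).

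Organ lists moved unevenly. Of 31 hepatocyte genes 10 rose and 6 fell, or 11 and 9 with p adjusted over the list alone, with fibrinogen genes FGB (ENSDARG00000008969) (1.22 ± 0.101, adjusted p = 2.51e-06) and FGG (ENSDARG00000037281) (1.2 ± 0.0981, adjusted p = 2.51e-06) and the complement gene c3a.1 (ENSDARG00000012694) (2.24 ± 0.205, adjusted p = 7.06e-06) higher while fabp10a was lower. The Hepatocyte list had a camera adjusted p = 0.00354, and adjusted p = 0.328 with an estimated correlation. Their median log2 fold change was -0.003 and their mean 0.095, against an upward call, lost with the replicate block (adjusted p = 0.0807), with limma-voom (adjusted p = 0.106) and without yap mutant 3 (adjusted p = 0.0597). Of 26 exocrine pancreas genes 0 rose and 2 fell, or 0 and 10 with p adjusted over the list alone. The Exocrine pancreas list had a camera adjusted p = 4.26e-07, and adjusted p = 0.357 with an estimated correlation. Of 31 intestinal genes 0 rose and 2 fell, or 0 and 2 with p adjusted over the list alone. The Intestinal epithelium list had a camera adjusted p = 1e-05, and adjusted p = 0.427 with an estimated correlation. Calls lost in some fits without 1 library included CPB1 (ENSDARG00000045442) in 7 (adjusted p = 0.0503 to 0.129), ANPEP (ENSDARG00000036809) in 6 (0.0637 to 0.113) and ANPEP (ENSDARG00000097285) in 7 (0.0511 to 0.0845). With the 8 libraries alone these 3 were lost (adjusted p = 0.0858, 0.0573 and 0.0536), and the first and last also with DESeq2 (0.0633 and 0.0712). The mean log2 difference of exocrine genes from the WT mean overlapped, at -0.77 to 0.78 in WT and -2.13 to -0.12 in the yap mutant. Each yap mutant library lay below the WT library of its number. Of 33 endothelial genes 10 rose and 0 fell, or 15 and 0 with p adjusted over the list alone, including the tight-junction gene CLDN5 (ENSDARG00000014059) (1.1 ± 0.0986, adjusted p = 5.77e-06). The Endothelium list had a camera adjusted p = 4.03e-07, and adjusted p = 0.252 with an estimated correlation. Of 38 epidermal genes 12 rose and 1 fell, or 15 and 3 with p adjusted over the list alone, including the keratin gene krt18a.1 (ENSDARG00000018404) (0.90 ± 0.124, adjusted p = 0.000308). The Epidermis list had a camera adjusted p = 4.83e-05, and adjusted p = 0.357 with an estimated correlation. Of 47 skeletal muscle genes 5 rose and 1 fell, or 10 and 1 with p adjusted over the list alone, including the creatine kinase gene ckma (ENSDARG00000035327) (0.63 ± 0.0966, adjusted p = 0.000729). The Skeletal muscle list had a camera adjusted p = 0.00166, and adjusted p = 0.571 with an estimated correlation. Of 41 oxidative phosphorylation genes 0 rose and 1 fell, or 0 and 0 with p adjusted over the list alone. The Oxidative phosphorylation list had a camera adjusted p = 8.07e-07, and adjusted p = 0.562 with an estimated correlation. The 1 gene, COX4I1 (ENSDARG00000032970), lost its call in 8 of the fits without 1 library (adjusted p = 0.0533 to 0.134) and with the 8 libraries alone (adjusted p = 0.0817).

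The remaining lists were not called in the yap mutant. In the Glutamine and amino acid metabolism list 5 rose and 2 fell of 30 (camera adjusted p = 0.269) and in Cholesterol synthesis 4 rose and 0 fell of 26 (camera adjusted p = 0.0734). In the Ribosome biogenesis list 2 rose and 0 fell of 44 (camera adjusted p = 0.0851) and in Ribosomal proteins 0 rose and 0 fell of 59 (camera adjusted p = 0.775). In the Circadian clock list 2 rose and 1 fell of 31 (camera adjusted p = 0.309) and in Endocrine pancreas 3 rose and 1 fell of 16 (camera adjusted p = 0.21). In the Pigment cells list 2 rose and 2 fell of 30 (camera adjusted p = 0.462) and in Cardiac muscle 4 rose and 0 fell of 22 (camera adjusted p = 0.105). In the Cartilage and notochord list 2 rose and 3 fell of 30 (camera adjusted p = 0.564) and in Bone and tooth 0 rose and 2 fell of 17 (camera adjusted p = 0.0973). In the Fin fold list 0 rose and 0 fell of 26 (camera adjusted p = 0.861) and in Erythroid 1 rose and 3 fell of 21 (camera adjusted p = 0.816). In the Glia list 3 rose and 2 fell of 28 (camera adjusted p = 0.269) and in Pronephros 6 rose and 1 fell of 41 (camera adjusted p = 0.104). Median, mean and test differed in sign for gluconeogenesis (median -0.03, mean 0.052, upward), purine synthesis (median -0.076, mean 0.043, downward) and endocrine pancreas (median -0.024, mean 0.13, upward).

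**Figure D2:**
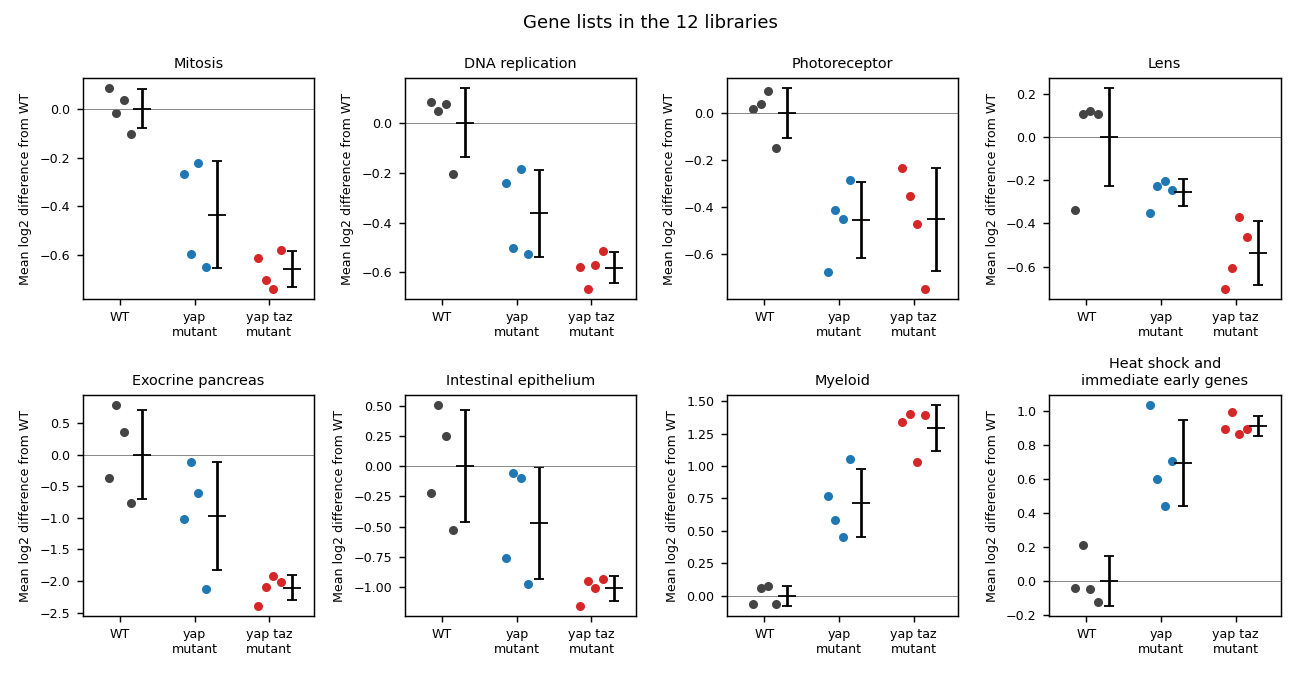
Mean log2 difference from the WT mean over the members of 8 gene lists (linear axes, 1 point per library, mean ± SD of 4 libraries beside the points of each genotype). The 4 yap taz mutant libraries lay below all WT libraries in the mitosis, DNA replication, photoreceptor, lens, exocrine and intestinal panels and above them in the myeloid and immediate-early panels, and the exocrine score of WT ran from -0.77 to 0.78.

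With mutations in both genes more genes changed, with the pancreatic digestive enzymes the largest falls. The comparison of the yap taz mutant with WT asks what differs in larvae homozygous for both mutations. Transcripts of pancreatic elastase genes fell from 186 ± 135 CPM to 3.19 ± 1.23 CPM for ela2 (ENSDARG00000056744) (-5.87 ± 0.764, adjusted p = 3.64e-05) and from 150 ± 122 CPM to 3.05 ± 1.71 CPM for ela2l (ENSDARG00000056765) (-5.64 ± 0.725, adjusted p = 3.16e-05), and the amylase gene amy2a (ENSDARG00000013856) fell from 47.8 ± 25.7 CPM to 2.02 ± 0.897 CPM (-4.56 ± 0.677, adjusted p = 0.000121). The cytokine genes again rose, il1b from 0.409 ± 0.273 CPM to 12.7 ± 3.81 CPM and il11a from 0.146 ± 0.114 CPM to 8.07 ± 1.89 CPM, and the protease genes mmp13a (4.27 ± 0.41, adjusted p = 1.91e-06) and MMP9 (4.19 ± 0.423, adjusted p = 3.17e-06) were among the largest rises.

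In all, 5391 of 19493 genes differed between the yap taz mutant and WT, 2701 higher and 2690 lower, with 724 and 584 at least 2-fold (edgeR quasi-likelihood test, 4 against 4 libraries). The groups did not overlap for 28.9% of genes, against 2.86% by chance. Against a minimum fold of 1.5 the count was 999 (591 higher, 408 lower), and without single libraries it ran from 4452 to 5731. Camera called 23 of 41 lists with the preset correlation and 0 with an estimated one (8 at an unadjusted p under 0.05), and other splits of these 8 libraries called 2 to 22 lists.

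Most exocrine pancreas and intestinal genes fell in the yap taz mutant. Of 26 exocrine pancreas genes 0 rose and 21 fell, or 0 and 22 with p adjusted over the list alone, with a median log2 fold change of -1.93. The Exocrine pancreas list had a camera adjusted p = 6.51e-12, and adjusted p = 0.267 with an estimated correlation. Relative to the WT mean these genes scored -2.39 to -1.92 in the 4 yap taz mutant libraries, below each WT library. All larvae were of 1 age, and the hatching enzyme genes he1.2 (5.15 ± 0.684, adjusted p = 4.4e-05) and he1.1 (3.95 ± 0.619, adjusted p = 0.000199), chosen after their values were seen, were also higher. Of 31 intestinal genes 0 rose and 23 fell, or 0 and 23 with p adjusted over the list alone, including the aminopeptidase gene ANPEP (ENSDARG00000097285) (-1.85 ± 0.16, adjusted p = 6.8e-07) and the fat-absorption enzyme gene MOGAT2 (ENSDARG00000019228) (-1.78 ± 0.27, adjusted p = 0.00015). The Intestinal epithelium list had a camera adjusted p = 2.42e-10, and adjusted p = 0.267 with an estimated correlation. Of 16 endocrine genes 5 rose and 0 fell, or 5 and 0 with p adjusted over the list alone. The Endocrine pancreas list had a camera adjusted p = 0.00215, and adjusted p = 0.0881 with an estimated correlation. The glucagon genes GCG (ENSDARG00000040907) (2.48 ± 0.156, adjusted p = 2.81e-08) and gcga (ENSDARG00000079296) (2.17 ± 0.192, adjusted p = 8.54e-07) rose, and the insulin gene ins (ENSDARG00000035350) rose from 17.1 ± 2.79 CPM to 25.5 ± 3.43 CPM (0.58 ± 0.135, adjusted p = 0.00407). Of 31 hepatocyte genes 14 rose and 9 fell, or 14 and 10 with p adjusted over the list alone, with FGB (1.73 ± 0.102, adjusted p = 2.04e-08) and c3a.1 (2.57 ± 0.207, adjusted p = 3.46e-07) higher, a list call lost with limma-voom (adjusted p = 0.0651). The Hepatocyte list had a camera adjusted p = 0.0012, and adjusted p = 0.267 with an estimated correlation.

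Nearly the whole mitosis list fell. Of 37 genes 0 rose and 35 fell, or 0 and 37 with p adjusted over the list alone, including the kinesin gene kif20a (ENSDARG00000044491) (-0.89 ± 0.102, adjusted p = 1.02e-05) and CCNB1 (ENSDARG00000051923), the mitotic cyclin gene (-0.92 ± 0.106, adjusted p = 1.05e-05). The Mitosis list had a camera adjusted p = 5.2e-21, and adjusted p = 0.241 with an estimated correlation. Of 44 DNA replication genes 0 rose and 35 fell, or 0 and 40 with p adjusted over the list alone, including MCM6 (-0.81 ± 0.0864, adjusted p = 5.07e-06) and MCM3 (ENSDARG00000024204) (-0.91 ± 0.111, adjusted p = 2.06e-05). The DNA replication list had a camera adjusted p = 9.61e-17, and adjusted p = 0.241 with an estimated correlation. Of 44 ribosome biogenesis genes 2 rose and 9 fell, or 2 and 9 with p adjusted over the list alone, among them the nucleolar gene npm1a (ENSDARG00000014329) (-0.73 ± 0.111, adjusted p = 0.000154). The Ribosome biogenesis list had a camera adjusted p = 0.00708, and adjusted p = 0.558 with an estimated correlation. Of 41 oxidative phosphorylation genes 0 rose and 24 fell, or 0 and 31 with p adjusted over the list alone, including atp5mc1 (ENSDARG00000056008), a subunit of the ATP synthase (-0.66 ± 0.119, adjusted p = 0.000645), and the share of mitochondrial-genome counts was lower in every yap taz mutant library than in every WT library. The Oxidative phosphorylation list had a camera adjusted p = 4.88e-08, and adjusted p = 0.519 with an estimated correlation.

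Glucose genes again moved both ways. Of 15 glucose transporter genes 5 rose and 3 fell, or 7 and 3 with p adjusted over the list alone (camera adjusted p = 0.401). SLC2A1 (ENSDARG00000001437) fell to 1.62 ± 0.516 CPM (-2.37 ± 0.234, adjusted p = 2.58e-06), while slc2a3b (2.21 ± 0.31, adjusted p = 7.46e-05) and SLC2A6 (ENSDARG00000058731) (2.28 ± 0.348, adjusted p = 0.000156) rose. Of 33 glycolysis genes 6 rose and 9 fell, or 6 and 9 with p adjusted over the list alone (camera adjusted p = 0.192). The lactate dehydrogenase gene LDHA (ENSDARG00000101251) (-0.68 ± 0.0973, adjusted p = 8.26e-05) and the muscle phosphofructokinase gene PFKM (ENSDARG00000060797) (-0.92 ± 0.136, adjusted p = 0.000116) fell, while HK2 rose (0.74 ± 0.113, adjusted p = 0.000159). PCK1 rose to 630 ± 73.5 CPM (2.23 ± 0.125, adjusted p = 1.46e-08), in a gluconeogenesis list where 4 rose and 2 fell of 13 (camera adjusted p = 0.0954).

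Nucleotide synthesis genes again moved in both directions. Of 19 pyrimidine and deoxynucleotide genes 1 rose and 8 fell, or 1 and 8 with p adjusted over the list alone, with RRM1 (-0.88 ± 0.105, adjusted p = 1.66e-05), TYMS (-0.79 ± 0.118, adjusted p = 0.000127) and the dihydrofolate reductase gene dhfr (ENSDARG00000004251) (-1.02 ± 0.162, adjusted p = 0.000221) lower and CTPS1 (ENSDARG00000098386), a CTP synthase gene, higher (0.78 ± 0.123, adjusted p = 0.000216). The Pyrimidine and deoxynucleotide synthesis list had a camera adjusted p = 0.00449, and adjusted p = 0.241 with an estimated correlation. Of 17 purine genes 4 rose and 5 fell, or 4 and 5 with p adjusted over the list alone (camera adjusted p = 0.683). PPAT (1.01 ± 0.156, adjusted p = 0.000176), PAICS (1.08 ± 0.211, adjusted p = 0.00123) and ATIC (ENSDARG00000016706) (0.99 ± 0.191, adjusted p = 0.00111) of the inosine monophosphate branch rose, while ADSS1 (ENSDARG00000099517), an adenylosuccinate synthase gene, fell (-1.13 ± 0.197, adjusted p = 0.000482). Of 20 serine and one-carbon genes 6 rose and 4 fell, or 6 and 5 with p adjusted over the list alone (camera adjusted p = 0.401), with GLDC (2.49 ± 0.166, adjusted p = 4.89e-08) and MTHFD1L (ENSDARG00000042221) (1.04 ± 0.157, adjusted p = 0.000145) higher.

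**Figure D3:**
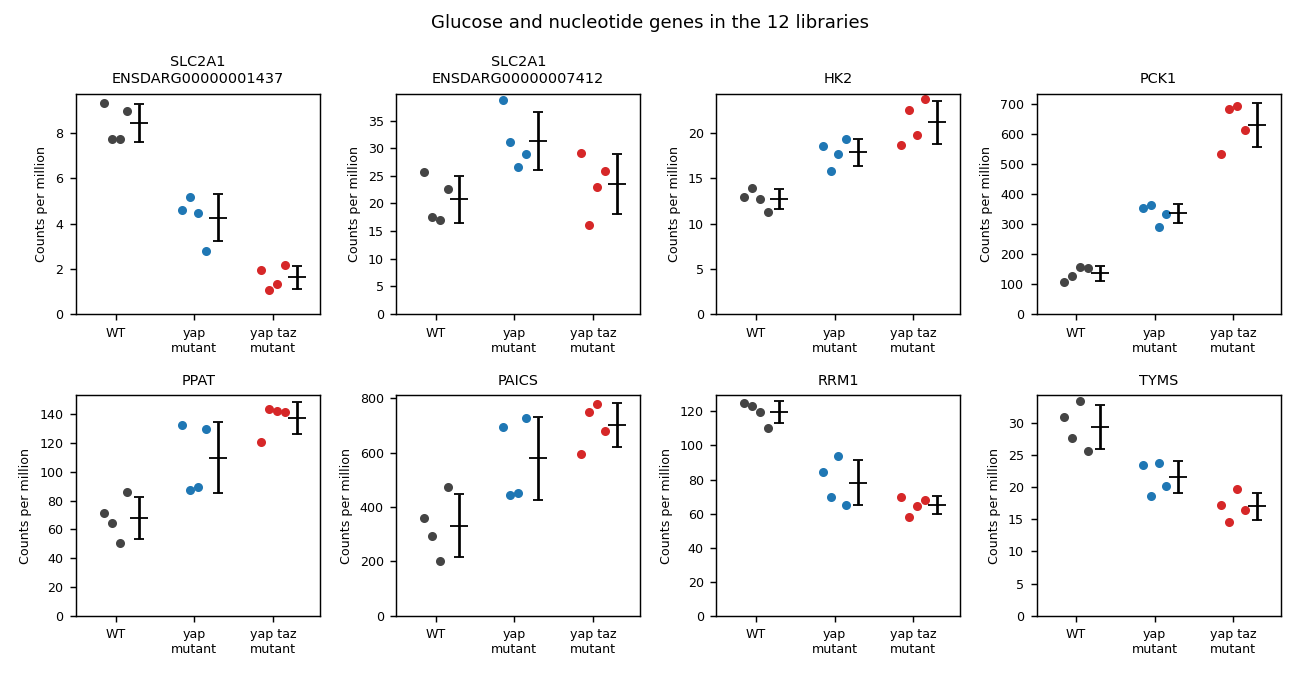
CPM of 8 glucose and nucleotide genes on linear axes from 0, with 1 point per library and the mean ± SD of the 4 libraries beside the points of each genotype. PCK1 rose from 135 CPM in WT to 335 and 630 CPM in the mutants, RRM1 fell from 120 to 78.1 and 65.1 CPM, and the 2 genes with the symbol SLC2A1 had different patterns.

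In the YAP/TAZ target signature more genes again rose than fell. Of 30 genes 12 rose and 2 fell, or 13 and 2 with p adjusted over the list alone. The YAP/TAZ target signature list had a camera adjusted p = 0.000348, and adjusted p = 0.284 with an estimated correlation. CCN2 (1.16 ± 0.11, adjusted p = 1.71e-06) and amotl2b (1.27 ± 0.13, adjusted p = 3.46e-06) rose, while ANKRD1 (ENSDARG00000076192), an ankyrin-repeat gene whose symbol is shared, fell from 60.8 ± 8.21 CPM to 9.58 ± 0.993 CPM (-2.67 ± 0.256, adjusted p = 1.94e-06). Stress genes rose more often than they fell: of 32 heat shock and immediate-early genes 16 rose and 4 fell, or 19 and 5 with p adjusted over the list alone, led by SOCS3 (3.08 ± 0.135, adjusted p = 2.03e-09) and ATF3 (ENSDARG00000007823) (2.8 ± 0.194, adjusted p = 8.25e-08). The Heat shock and immediate early genes list had a camera adjusted p = 1.08e-10, and adjusted p = 0.0881 with an estimated correlation. Of 28 p53-response genes 14 rose and 2 fell, or 17 and 2 with p adjusted over the list alone, including rps27l (ENSDARG00000100513) (1.06 ± 0.118, adjusted p = 8.02e-06). The p53 response list had a camera adjusted p = 1.87e-06, and adjusted p = 0.0881 with an estimated correlation. Of 27 genes of the integrated stress response 14 rose and 3 fell, or 15 and 3 with p adjusted over the list alone, with CEBPB at 2.7 ± 0.203 (adjusted p = 1.68e-07). The Integrated stress response list had a camera adjusted p = 0.000123, and adjusted p = 0.241 with an estimated correlation. Of 32 myeloid genes 24 rose and 1 fell, or 26 and 1 with p adjusted over the list alone, including the chemokine receptor gene CXCR4 (ENSDARG00000057633) (2.18 ± 0.152, adjusted p = 8.25e-08) and the neutrophil gene npsn (ENSDARG00000010423) (1.17 ± 0.115, adjusted p = 2.5e-06). The Myeloid list had a camera adjusted p = 6.57e-18, and adjusted p = 0.0881 with an estimated correlation.

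Among eye and pigment genes more fell than rose here too. Of 17 retinal pigment epithelium genes 2 rose and 9 fell, or 2 and 12 with p adjusted over the list alone, with RPE65 (-2.64 ± 0.196, adjusted p = 1.54e-07) and the melanosome gene pmelb (ENSDARG00000033760) (-2.75 ± 0.236, adjusted p = 6.45e-07) lower. The Retinal pigment epithelium list had a camera adjusted p = 7.73e-05, and adjusted p = 0.138 with an estimated correlation. Of 48 photoreceptor genes 2 rose and 24 fell, or 2 and 25 with p adjusted over the list alone, and sagb stood at 30.6 ± 7.05 CPM (-1.29 ± 0.139, adjusted p = 6.04e-06). The Photoreceptor list had a camera adjusted p = 3.13e-08, and adjusted p = 0.319 with an estimated correlation. Of 34 lens genes 3 rose and 20 fell, or 3 and 22 with p adjusted over the list alone, including the lens water channel gene MIP (ENSDARG00000037285) (-1.36 ± 0.122, adjusted p = 9.17e-07). The Lens list had a camera adjusted p = 1.89e-11, and adjusted p = 0.267 with an estimated correlation. Of 30 pigment cell genes 3 rose and 8 fell, or 3 and 14 with p adjusted over the list alone, including the iridophore gene pnp4a (ENSDARG00000057575) (-1.7 ± 0.13, adjusted p = 2.01e-07) and the melanin synthesis gene DCT (ENSDARG00000006008) (-1.16 ± 0.15, adjusted p = 3.45e-05). The Pigment cells list had a camera adjusted p = 0.0012, and adjusted p = 0.342 with an estimated correlation.

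The skeletal muscle, endothelial, matrix, epidermal and neuronal lists were also called. Of 47 skeletal muscle genes 19 rose and 4 fell, or 19 and 4 with p adjusted over the list alone, with ckma at 1.17 ± 0.0975 (adjusted p = 4.89e-07). The Skeletal muscle list had a camera adjusted p = 0.00296, and adjusted p = 0.558 with an estimated correlation. Of 33 endothelial genes 14 rose and 3 fell, or 15 and 4 with p adjusted over the list alone, with the scavenger receptor gene lyve1a (ENSDARG00000075833) higher (2.33 ± 0.202, adjusted p = 6.8e-07). The Endothelium list had a camera adjusted p = 0.000666, and adjusted p = 0.267 with an estimated correlation. Of 53 matrix genes 9 rose and 18 fell, or 11 and 20 with p adjusted over the list alone, with collagen col6a1 (ENSDARG00000074908) (-0.85 ± 0.0791, adjusted p = 1.5e-06) and versican vcanb (ENSDARG00000009401) (-1.26 ± 0.114, adjusted p = 1.01e-06) lower. The Extracellular matrix list had a camera adjusted p = 0.0271, and adjusted p = 0.578 with an estimated correlation. Of 38 epidermal genes 16 rose and 7 fell, or 18 and 8 with p adjusted over the list alone, with E-cadherin cdh1 (ENSDARG00000102750) higher (1.04 ± 0.107, adjusted p = 3.62e-06). The Epidermis list had a camera adjusted p = 0.0149, and adjusted p = 0.558 with an estimated correlation. Of 65 neuronal genes 2 rose and 15 fell, or 2 and 15 with p adjusted over the list alone, with tubb5 lower (-0.89 ± 0.15, adjusted p = 0.000392). The Neuron list had a camera adjusted p = 0.0276, and adjusted p = 0.558 with an estimated correlation. The matrix call was lost without WT 4, yap mutant 3, yap taz mutant 1, yap taz mutant 2 or yap taz mutant 4 (adjusted p = 0.0537 to 0.155) and with the 8 libraries alone (adjusted p = 0.122), the epidermal call without WT 1, yap taz mutant 2 or yap taz mutant 3 (adjusted p = 0.0514 to 0.174), and the neuronal call without WT 1, WT 4, yap taz mutant 2 or yap taz mutant 4 (adjusted p = 0.0631 to 0.0946).

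The remaining lists were not called in the yap taz mutant. In the Hippo pathway and TEAD list 6 rose and 0 fell of 29 (camera adjusted p = 0.128) and in Pentose phosphate pathway 2 rose and 3 fell of 10 (camera adjusted p = 0.275). In the Glutamine and amino acid metabolism list 7 rose and 6 fell of 30 (camera adjusted p = 0.833) and in Cholesterol synthesis 3 rose and 3 fell of 26 (camera adjusted p = 0.797). In the Ribosomal proteins list 1 rose and 1 fell of 59 (camera adjusted p = 0.677) and in Circadian clock 7 rose and 2 fell of 31 (camera adjusted p = 0.153). In the Cardiac muscle list 2 rose and 8 fell of 22 (camera adjusted p = 0.153) and in Cartilage and notochord 5 rose and 7 fell of 30 (camera adjusted p = 0.477). In the Bone and tooth list 2 rose and 5 fell of 17 (camera adjusted p = 0.205) and in Fin fold 4 rose and 4 fell of 26 (camera adjusted p = 0.725). In the Erythroid list 1 rose and 6 fell of 21 (camera adjusted p = 0.0537) and in Glia 4 rose and 8 fell of 28 (camera adjusted p = 0.22). In the Pronephros list 13 rose and 10 fell of 41 (camera adjusted p = 0.505). Median, mean and test differed in sign for purine synthesis (median -0.16, mean 0.0017, downward), serine and one-carbon metabolism (median -0.026, mean 0.14, upward), glutamine and amino acid metabolism (median -0.029, mean -0.045, upward) and fin fold (median 0.12, mean 0.03, downward).

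Between the mutants most genes of each list did not pass the test: 11 of 34 lens, 7 of 30 pigment cell and 8 of 53 matrix genes were lower in the yap taz mutant, and 10 of 32 myeloid genes were higher. The comparison of the yap taz mutant with the yap mutant asks what the taz mutation adds to the yap mutation. The transporter gene slc12a10.3 (ENSDARG00000055253) rose from 2.43 ± 0.821 CPM to 11.1 ± 1.43 CPM (2.19 ± 0.202, adjusted p = 5.2e-05) and the brevican gene bcan (ENSDARG00000099412) from 41.9 ± 19.9 CPM to 147 ± 46.5 CPM (1.81 ± 0.325, adjusted p = 0.00479). The prolactin gene prl (ENSDARG00000037946) rose from 14.1 ± 6.24 CPM to 37.4 ± 7.13 CPM (1.41 ± 0.22, adjusted p = 0.00218). The potassium channel gene KCNJ1 (ENSDARG00000090866) fell from 4.24 ± 1.06 CPM to 0.75 ± 0.436 CPM (-2.5 ± 0.405, adjusted p = 0.0027). ANKRD1 (-1.94 ± 0.261, adjusted p = 0.000901) and SLC2A1 (ENSDARG00000001437) (-1.38 ± 0.253, adjusted p = 0.00562) fell and PCK1 (0.91 ± 0.12, adjusted p = 0.000783) and GLDC (1.05 ± 0.156, adjusted p = 0.00147) rose, and for all of these the test separated each genotype from the next, narrowly so for ANKRD1 in the yap mutant.

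In all, 814 of 19493 genes differed between the mutants, 374 higher and 440 lower in the yap taz mutant, with 79 and 134 at least 2-fold (edgeR quasi-likelihood test, 4 against 4 libraries). The groups did not overlap for 10.8% of genes, against 2.86% by chance. The count was 22 against a minimum fold of 1.5 (11 higher, 11 lower), and 441 without yap taz mutant 2, 468 without yap mutant 2, 497 without yap taz mutant 4 and 538 without yap mutant 3. Camera called 18 of 41 lists with the preset correlation and 0 with an estimated one (6 at an unadjusted p under 0.05), and other splits of these 8 libraries called 7 to 21 lists.

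In the matrix, pigment, lens, cardiac and erythroid lists more genes fell than rose, and most members did not pass the test. Of 53 matrix genes 1 rose and 8 fell, or 1 and 17 with p adjusted over the list alone, including THBS4 (ENSDARG00000020072) (-0.74 ± 0.0816, adjusted p = 0.000217), vcanb (-0.98 ± 0.114, adjusted p = 0.000296) and col6a1 (-0.57 ± 0.079, adjusted p = 0.00114). The Extracellular matrix list had a camera adjusted p = 1.99e-11, and adjusted p = 0.313 with an estimated correlation. Of 30 pigment cell genes 0 rose and 7 fell, or 1 and 9 with p adjusted over the list alone, with pnp4a (-1.05 ± 0.134, adjusted p = 0.000689) and DCT (-0.89 ± 0.152, adjusted p = 0.00362) lower. The Pigment cells list had a camera adjusted p = 1.69e-06, and adjusted p = 0.297 with an estimated correlation. Of 34 lens genes 0 rose and 11 fell, or 2 and 17 with p adjusted over the list alone. The Lens list had a camera adjusted p = 2.7e-08, and adjusted p = 0.416 with an estimated correlation. Of 17 retinal pigment epithelium genes 2 rose and 4 fell, or 3 and 5 with p adjusted over the list alone. The Retinal pigment epithelium list had a camera adjusted p = 0.000583, and adjusted p = 0.256 with an estimated correlation. The lens gene MIP (ENSDARG00000037285) (-0.94 ± 0.122, adjusted p = 0.000758) and pmelb (-2.09 ± 0.246, adjusted p = 0.000296) were lower. Of 22 cardiac genes 0 rose and 4 fell, or 0 and 10 with p adjusted over the list alone, including the myosin light chain gene MYL7 (ENSDARG00000019096) (-0.95 ± 0.147, adjusted p = 0.00196). The Cardiac muscle list had a camera adjusted p = 3.1e-06, and adjusted p = 0.256 with an estimated correlation. Of 21 erythroid genes 0 rose and 3 fell, or 0 and 8 with p adjusted over the list alone, including the anion exchanger gene SLC4A1 (ENSDARG00000012881) (-1.03 ± 0.149, adjusted p = 0.00142). The Erythroid list had a camera adjusted p = 0.000128, and adjusted p = 0.361 with an estimated correlation.

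In the digestive, cell division, endocrine, myeloid, immediate-early and p53 lists most members did not pass the test either. Of 26 exocrine genes 0 rose and 5 fell, or 0 and 11 with p adjusted over the list alone, with ela2 (-4.41 ± 0.771, adjusted p = 0.00406) and ela2l (-3.98 ± 0.743, adjusted p = 0.00633) lower, neither past the threshold with limma-voom (adjusted p = 0.112 and 0.107). The Exocrine pancreas list had a camera adjusted p = 1.31e-10, and adjusted p = 0.378 with an estimated correlation. Of 31 intestinal genes 0 rose and 3 fell, or 0 and 9 with p adjusted over the list alone. The Intestinal epithelium list had a camera adjusted p = 1.66e-08, and adjusted p = 0.416 with an estimated correlation. Of 16 endocrine genes 2 rose and 0 fell, or 5 and 0 with p adjusted over the list alone, with GCG higher (0.92 ± 0.139, adjusted p = 0.00167). The Endocrine pancreas list had a camera adjusted p = 0.000128, and adjusted p = 0.0677 with an estimated correlation. Of 37 mitosis genes 0 rose and 2 fell, or 0 and 7 with p adjusted over the list alone. The Mitosis list had a camera adjusted p = 1.38e-07, and adjusted p = 0.485 with an estimated correlation. Of 44 DNA replication genes 0 rose and 5 fell, or 0 and 11 with p adjusted over the list alone. The DNA replication list had a camera adjusted p = 2.26e-07, and adjusted p = 0.485 with an estimated correlation. CCNB1 (-0.56 ± 0.107, adjusted p = 0.00752) and the maintenance methyltransferase gene DNMT1 (ENSDARG00000030756) (-0.43 ± 0.0898, adjusted p = 0.0123) were lower. Of 32 myeloid genes 10 rose and 0 fell, or 18 and 0 with p adjusted over the list alone, with npsn higher (0.86 ± 0.114, adjusted p = 0.000829). The Myeloid list had a camera adjusted p = 2.99e-13, and adjusted p = 0.105 with an estimated correlation. Of 32 heat shock and immediate-early genes 7 rose and 2 fell, or 10 and 3 with p adjusted over the list alone, with JUNB (ENSDARG00000104773) higher (1.09 ± 0.159, adjusted p = 0.00142). The Heat shock and immediate early genes list had a camera adjusted p = 0.00172, and adjusted p = 0.416 with an estimated correlation. Of 28 p53-response genes 5 rose and 0 fell, or 7 and 0 with p adjusted over the list alone, with the pro-apoptotic gene bbc3 (ENSDARG00000069282) higher (0.80 ± 0.147, adjusted p = 0.00562). The p53 response list had a camera adjusted p = 7.22e-07, and adjusted p = 0.105 with an estimated correlation.

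In 4 further called lists the call was lost in at least 1 fit without a single library. Of 31 hepatocyte genes 3 rose and 1 fell, or 7 and 3 with p adjusted over the list alone, a call lost without WT 1, yap mutant 4, yap taz mutant 2 or yap taz mutant 3 (adjusted p = 0.0518 to 0.365) and with the 8 libraries alone (adjusted p = 0.0643). The Hepatocyte list had a camera adjusted p = 0.0366, and adjusted p = 0.485 with an estimated correlation. Of 26 cholesterol synthesis genes 1 rose and 0 fell, or 1 and 3 with p adjusted over the list alone, while the list was called downward (median log2 fold change -0.37), a call lost without yap mutant 2 (adjusted p = 0.341). The Cholesterol synthesis list had a camera adjusted p = 0.00892, and adjusted p = 0.767 with an estimated correlation. Of 41 oxidative phosphorylation genes 0 rose and 0 fell, or 0 and 0 with p adjusted over the list alone, with the list called downward (median -0.14), a call lost without yap mutant 3 (adjusted p = 0.394). The Oxidative phosphorylation list had a camera adjusted p = 0.000678, and adjusted p = 0.767 with an estimated correlation. Of 44 ribosome biogenesis genes 0 rose and 1 fell, or 0 and 2 with p adjusted over the list alone, lost without yap taz mutant 1 (adjusted p = 0.12). The Ribosome biogenesis list had a camera adjusted p = 0.0156, and adjusted p = 0.767 with an estimated correlation. The remaining lists were not called between the mutants. In the YAP/TAZ target signature list 1 rose and 2 fell of 30 (camera adjusted p = 0.465) and in Hippo pathway and TEAD 0 rose and 0 fell of 29 (camera adjusted p = 0.831). In the Glucose transporters list 2 rose and 2 fell of 15 (camera adjusted p = 0.861) and in Glycolysis 0 rose and 3 fell of 33 (camera adjusted p = 0.233). In the Gluconeogenesis list 1 rose and 0 fell of 13 (camera adjusted p = 0.0687) and in Pentose phosphate pathway 0 rose and 0 fell of 10 (camera adjusted p = 0.578). In the Purine synthesis list 0 rose and 1 fell of 17 (camera adjusted p = 0.649) and in Pyrimidine and deoxynucleotide synthesis 1 rose and 0 fell of 19 (camera adjusted p = 0.0751). In the Serine and one-carbon metabolism list 2 rose and 2 fell of 20 (camera adjusted p = 0.655) and in Glutamine and amino acid metabolism 1 rose and 1 fell of 30 (camera adjusted p = 0.384). In the Ribosomal proteins list 0 rose and 0 fell of 59 (camera adjusted p = 0.314) and in Integrated stress response 4 rose and 2 fell of 27 (camera adjusted p = 0.123). In the Circadian clock list 0 rose and 0 fell of 31 (camera adjusted p = 0.251) and in Photoreceptor 1 rose and 4 fell of 48 (camera adjusted p = 0.831). In the Skeletal muscle list 3 rose and 1 fell of 47 (camera adjusted p = 0.237) and in Cartilage and notochord 0 rose and 1 fell of 30 (camera adjusted p = 0.638). In the Bone and tooth list 0 rose and 1 fell of 17 (camera adjusted p = 0.831) and in Epidermis 1 rose and 0 fell of 38 (camera adjusted p = 0.72). In the Fin fold list 0 rose and 4 fell of 26 (camera adjusted p = 0.499) and in Endothelium 2 rose and 2 fell of 33 (camera adjusted p = 0.978). In the Neuron list 0 rose and 1 fell of 65 (camera adjusted p = 0.831) and in Glia 1 rose and 2 fell of 28 (camera adjusted p = 0.55). In the Pronephros list 1 rose and 6 fell of 41 (camera adjusted p = 0.55). Median, mean and test differed in sign for cartilage and notochord (median 0.048, mean -0.082, downward), fin fold (median 0.0042, mean 0.0031, downward), endothelium (median 0.062, mean -8.9e-06, upward), neuron (median 0.016, mean -0.0021, upward) and pronephros (median 0.021, mean -0.11, downward).

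With the same WT libraries in both comparisons, most genes changed in the yap mutant changed the same way in the yap taz mutant. Of the 1780 genes changed in the yap mutant and the 5391 in the yap taz mutant, 1585 were shared in direction, 995 higher and 590 lower in both, and 2 were opposite. Among the higher genes were PCK1, GLDC, SOCS3, MMP9 and CCN2, and among the lower RRM1, sagb, RPE65, MCM6 and CDC20. Independent lists of these sizes would share 154 higher and 91.8 lower genes. Across the 19493 genes the fold changes against WT correlated at 0.802 with a covariance of 0.18, genes not being independent replicates. In 20 simulations of unchanged groups, WT redrawn too, at most 2 genes were called in either comparison, so they give no shared count to compare. Simulated correlations were 0.479 to 0.504. Covariances, 0.0188 to 0.0211, were 0.16 under the observed. The simulations do not measure effects of the real WT libraries. With the WT libraries split 2 and 2 between the comparisons, the shared genes were 435 of 480 changed in the yap mutant, 488 of 576, 562 of 665, 595 of 704, 631 of 740 and 1142 of 2378 over the 6 assignments. In the last, where WT 2 and WT 3 stood against the yap mutant, most were not shared and 16 were opposite. The assignments had correlations of 0.553 to 0.693 and covariances of 0.141 to 0.17. The shared count was 877 without yap mutant 4, 892 without yap mutant 1, 988 without WT 3, 990 without WT 2, 2415 without yap mutant 3 and 141 against a minimum fold of 1.5.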

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

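Of the tests weighed in this part, those of a wrong genotype label, of a shared replicate number, of slower development and of more myeloid cells were chosen after the result was seen. A value was picked out when 1 of the 4 libraries of a genotype lay so far from the other 3 that its gap to the nearest, divided by the group's range, exceeded the 95% critical value of Dixon's test. Chance picks out about 1 group in 20. It picked out 0 of 9 groups of library measures, 7 of 123 groups of list scores (5.69%) and 34 of 693 groups of named genes (4.91%), which is about the share chance gives.

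Among the list scores, given as the mean log2 difference from the WT mean in the library that stood apart, these were glycolysis at -0.20, pyrimidine and deoxynucleotide synthesis at -0.16, extracellular matrix at 0.063 and cardiac muscle at -0.34 in the yap taz mutant. In WT they were DNA replication at -0.21 and lens at -0.34, and in the yap mutant pronephros at 0.25.

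Among the named genes 1 library stood apart, given here with its log2 CPM, in WT for isg15 -1.46, SOCS3 4.26, JUNB (ENSDARG00000104773) 5.26, csf1ra 2.46, CRYBA2 8.64, smyhc1 9.38, SLC1A2 9.40, NOP58 6.35, GNAT1 6.10, PDE6B 3.81, MIP (ENSDARG00000037285) 6.96, ALPL 5.66, bcan 6.29, cyp2x9 4.83 and DNMT1 6.12. The value of isg15 lies near the floor. In the yap mutant the genes were FN1 8.24, grk1b 4.63, GNAT1 5.65, pgam1a 6.48, BTG2 5.77 and MAP1B 4.85. In the yap taz mutant they were amotl2b 6.04, slc2a3b 2.69, PPAT 6.92, UCK2 4.99, hmgb2b 7.78, tnfrsf1a 5.38, CRYBA2 8.40, ANXA2 7.91, hemgn 3.94, slc2a15b 2.08, EIF4EBP3 6.80, MIP (ENSDARG00000037285) 5.32 and MIP (ENSDARG00000013963) 5.65.

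The falls of 21 of 26 exocrine pancreas and 23 of 31 intestinal genes in the yap taz mutant were weighed first. With RLE or upper-quartile scaling, close to TMM for all genes, both medians kept at least 100%, which leaves scaling by a few abundant genes open. Slower development of the whole larva may lower genes of late organs: the hatching enzyme genes he1.2 (5.15 ± 0.684, adjusted p = 4.4e-05) and he1.1 (3.95 ± 0.619, adjusted p = 0.000199) were higher in the yap taz mutant than in WT, with a median of 4.55. No larvae of another age are in the series, so slower development cannot be told apart from an effect on these organs. The genotype itself stays open as the biological explanation.

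The rises of 14 of 32 myeloid genes in the yap mutant and of 24 in the yap taz mutant, where 1 fell, were weighed second. With the other scalings, close to TMM, the median of the list kept at least 98.2%, which leaves scaling by a few abundant genes open. More myeloid cells may be present: 6 lineage genes of 8 listed could be tested, and their median log2 fold change was 1.19 in the yap taz mutant and 0.742 in the yap mutant. All of them are members of the list whose rise prompted the test, so their rise cannot support this and it stays open. The range was 0.146 (lyz, adjusted p = 0.609) to 1.38 in the yap taz mutant and -0.55 (lyz, adjusted p = 0.0906) to 0.863 in the yap mutant, with the median taken over copies of a gene, chosen after a first version without it. Higher expression per cell stays open too, and 2 genes of the list are also in another list.

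The spread of the 4 yap mutant libraries along the first principal component, 37.3 units, was weighed last. A wrong label may cause this, but 0 yap mutant libraries had YAP1 in the WT range or WWTR1 in the range of another group, which argues against a swapped library, not one of mixed genotypes. Thinned to 7028251 counts each, the libraries kept 99.4% of the spread (37.1). The yap mutant totals were already 7824543 to 8033863, so thinning could hardly change it, which leaves depth open. A clutch or day shared by replicate number may contribute: of the 24 pairings of WT with yap mutant libraries, 2 gave differences with as small a range as the pairing by number (20.2), which leaves it open. No biological explanation was tested.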

How the results depend on the processing

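The block with the 8 libraries of WT and yap mutant alone was chosen after the data were seen, and all other settings before. Directions of named genes reversed in 0 fits. Outside the fits that leave out a library, 3019 values of named genes stayed on their side of the threshold, 12 moved past it and 39 fell short of it, and for lists 838, 8 and 7, with 8 reversed. Leaving out 1 library gave 4306, 9 and 293 for named genes, and 1386, 27 and 25 for lists, with 38 reversed. In all 12 such fits 99 of 131 named calls held in the yap mutant against WT, 144 of 146 in the yap taz mutant against WT and 72 of 97 between the mutants, and of list calls 18 of 21, 20 of 23 and 14 of 18.

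The 1780 genes of the yap mutant against WT became 2758 with the replicate block, 3380 with the block and the 8 libraries alone, 1163 with the 8 libraries alone and 142 against a minimum fold of 1.5, and 942 to 3041 without single libraries (yap mutant 1 942, yap mutant 4 954, WT 3 1059, WT 2 1076 and yap mutant 3 3041). Of the 1780, 1777 were also called with the block. The 5391 genes of the yap taz mutant against WT became 999 against a minimum fold of 1.5. The 814 genes between the mutants became 22 against a minimum fold of 1.5 and 441 to 1087 without single libraries (yap taz mutant 2 441, yap mutant 2 468, yap taz mutant 4 497 and yap mutant 3 538). The 1585 genes shared in direction became 141 against a minimum fold of 1.5 and 877 to 2415 without single libraries (yap mutant 4 877, yap mutant 1 892, WT 3 988, WT 2 990 and yap mutant 3 2415). With an estimated correlation 0 lists were called in each comparison in place of 21, 23 and 18. The test against a minimum fold asks for larger changes. The cause of the other shifts, which went up as well as down, was not tested. DESeq2 gave 1953, 5169 and 1071 genes and limma-voom 1717, 5303 and 745.

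The replicate block was also fitted where the numbers did not pair the libraries. It gave 6123 genes for the yap taz mutant against WT, 1443 between the mutants and 2360 shared in direction. Over all comparisons 10 of the 12 libraries correlated best with a library of their own number.

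The 46 reversals concern 19 list results, 0 of them a called list, with an adjusted p of at least 0.347. A reversal is a change in the direction of the camera test, and the median of a list can keep its sign. The medians (log2 fold change) were, with the replicate block, purine synthesis at -0.078 and fin fold at 0.059 in the yap mutant and glutamine and amino acid metabolism at -0.00700 in the yap taz mutant. Without a filter the medians were ribosomal proteins at 0.0012 in the yap mutant, and between the mutants bone and tooth at 0.011 and endothelium at 0.0498. With upper-quartile scaling endothelium between the mutants was at 0.046, and with limma-voom fin fold in the yap taz mutant at 0.13.

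Over the fits that leave out 1 library, the medians of lists with a reversal ranged as follows in the yap mutant against WT: purine synthesis -0.119 to -0.0378, ribosomal proteins -0.0289 to 0.0598, pigment cells -0.0896 to 0.0394, cartilage and notochord -0.109 to 0.0207, fin fold 0.00332 to 0.0775 and erythroid 0.0489 to 0.266. In the yap taz mutant against WT the ranges were glutamine and amino acid metabolism -0.0413 to 0.0343, cholesterol synthesis -0.399 to 0.0281 and ribosomal proteins -0.0536 to 0.0174. Between the mutants they were YAP/TAZ target signature 0.0231 to 0.106, Hippo pathway and TEAD -0.0885 to 0.0429, glucose transporters 0.0734 to 0.186, ribosomal proteins -0.0628 to 0.0013, photoreceptor 0.032 to 0.206, bone and tooth -0.113 to -0.016, epidermis -0.101 to -0.00768, endothelium 0.0148 to 0.112 and neuron -0.0341 to 0.0369.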

Other observations

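The tests in this part were planned, except that the comparison among 8 splits and 1 change to the haplotype test came after the results were seen. Other splits of the libraries of each comparison into 4 and 4 ask how often another grouping gives as many calls. For the yap mutant against WT the real split gave 1780 genes and the highest other 848, and 1 of 35 splits gave as many, a share under 0.05 if the libraries are not paired. The split with 848 genes set WT 1, WT 2, WT 3 and yap mutant 3 against the rest. Since the replicate numbers pair these libraries, the splits to compare are the 8 that part all 4 pairs, where the real one gave 1780 and the highest other 0. They are too few for a share under 0.05. For the yap taz mutant against WT the real split gave 5391 and the highest other 0, and between the mutants 814 and 5. Each is 1 of 35, but others mix genotypes, so chance is not excluded.

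Pairing aside, 4 of 35 splits of yap mutant and WT called as many lists (21 real, highest other 22). Between the mutants 3 of 35 did (18 real, highest other 21), so chance is not excluded for these 2 counts. In the yap taz mutant against WT 1 of 35 did (23 real, highest other 22), the smallest share possible, but by a margin of 1 list. That count was 20 to 24 without single libraries and 0 with an estimated correlation. With the preset one, splits mixed 2 to 2 called up to 18 lists and those 3 to 1, keeping part of the difference, 22. This bears on every list call.

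Of 100 splits of the 12 libraries into 3 groups of 4, drawn with pairing left aside, 2 gave as many genes shared in direction as the real 1585, the real one included (highest other 1634). The split with 1634 genes kept the 4 WT libraries together and mixed the mutants. The count therefore depends on WT being kept together, and it does not test the sharing between the mutants.

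A haplotype linked to a mutation might change genes near it. Gene order was taken from the supplied RefSeq gene table. Among the 50 tested genes nearest to yap1, 9 were called in the yap mutant against WT, where the median of windows elsewhere was 4 and 96% of windows held fewer. The bar set beforehand was 95%, so the window near yap1 met what a linked haplotype predicts. It could contribute there, and other reasons for changed neighbours were not tested. Among the 48 nearest to wwtr1, 4 were called between the mutants, where the median was 2 and 85.6% of windows held fewer, short of the bar but above the median, which leaves it open. In these spans 59.3% of 86 and 49% of 100 protein-coding genes had a value. A higher share with a value, first required, was not in the prediction and was dropped for counts above the bar.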
